A study of Rousettus aegyptiacus with 32 samples.

How the data were processed

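ATAC-seq libraries were made from nuclei released from cryopreserved tissue by Dounce homogenisation and passed through strainers, and RNA-seq libraries by poly(A) selection of RNA from flash-frozen tissue, per the labels. Samples were bulk tissue, so each value averages over the cell types present. Bowtie2, MACS2 and Salmon 1.5.2 are named in the submitters' processing notes, without roles. The aligner settings, the genome build and the annotation are not given in the sources used here.

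For ATAC-seq, the authors deposited 1 peak list per library in the narrowPeak layout, so peaks were called per library and not on pooled animals. Each row of the deposited lists gives a peak's position, its fold enrichment (a ratio over the caller's background) and its -log10 p and -log10 q. The lists held up to 300000 rows, and 15 of the 20 reached that number, while the others went down to a -log10 p of 2. Several rows share 1 interval with different summits. Rows with the same interval were merged, with the highest fold, -log10 p and -log10 q kept, and the 50000 strongest peaks of a library are its 50000 intervals with the highest -log10 p. Values of a peak were used to rank and filter peaks within a list. Where folds or -log10 p of different lists are set side by side, they are the caller's own, with no scaling between libraries. Coordinates are those of the files, counted from 1. Overlap was at least 1 base pair unless stated, and the lists were compared with bedtools 2.31.1 in Python 3.11.15. No read depth goes with the peak lists, so depth behind a peak is unknown here. Same-tissue overlap was tested with a 2-sided permutation of the tissue labels of bat 3, over 100000 rearrangements or, with 7 tissues or fewer, all of them. Counts of tissue-only regions carry no p and were set beside the same counts for mismatched libraries.

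For RNA-seq, the authors deposited Salmon output per library, with estimated counts (not whole numbers) and TPM for 55974 features. The deposited TPM values were not used here. The estimated counts were rounded to whole numbers. Features were kept with edgeR's filterByExpr on the 6 regions, which left 28713 features and at least 99.04% of the reads of each library. Libraries were scaled by TMM, and a model with 1 term per region was fitted to all 12 libraries with edgeR 4.0.16 (glmQLFit and glmQLFTest, 2-sided, R 4.3.3), with Benjamini-Hochberg adjustment over the features tested and a threshold of 0.05. The standard error of a log2 difference is its size divided by the square root of the F statistic. A group of regions entered as the mean of its regions. CPM are normalised by the TMM library sizes, and where all libraries of 1 side had 0 reads, the fold is a lower bound against 3 reads per library, also within the medians of called features. The animal numbers pair the libraries, since libraries with the same number come from the same animal, and the fit with the animal as a block was the alternative. As a check, the differences between bat 7 and bat 6 were correlated between regions across features, with r of -0.31 to 0.25 (median 0.062) over 15 pairs of regions, of which 4 were above 0.1. The highest correlation between any 2 RNA libraries was 0.867.

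Before the data were examined, the comparisons, tests, the rule for named features and most alternatives were fixed: DESeq2 1.42.0, RLE scaling, no count filter, only the regions compared, the replicate block, an offset for effective length, each library left out, and for peaks other thresholds and overlaps and each animal left out. The rule named features with an adjusted p under 0.05, a mean of at least 1 CPM and the same direction in both animals, by the size of the change. Since the IDs have no names, at most 2 per direction are given, where the rule allowed 12 and asked for a gene symbol, which no feature has. The regions given by position were chosen after their values were seen, as those with the highest weaker -log10 p among the libraries required to have the peak. The tests were written for genes and were run on features. The tests of gene lists, of peaks at promoters of named genes, and of links between genes and regions were not run, because they need gene names or an annotation of the build the peaks use. Sums of neighbouring features were formed from consecutive numbers with lengths within 10% of each other, which gave 39913 sums, 8963 of them of 2 or more features and the largest of 16. They stand in for genes only in part.

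The edgeR fit was tested on simulated counts with the means, spread and library sizes of the real features, with 200 features changed 2-, 4-, 8- or 16-fold per comparison (50 each). For cortex against striatum it called 1, 10 and 20 of the 50 features changed 4-, 8- and 16-fold, all in the right direction, and 2 unchanged features among 27796. The search for tissue-only regions, run on simulated lists for 4 tissues, found all 800 regions made for 1 tissue and 70 others. The simulated lists had no cut by rank and no limit of rows. This check therefore covers the overlap steps only and does not show how the search behaves under the thresholds of the real lists.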

Results

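Chromatin accessibility and gene expression were measured in tissues of the Egyptian fruit bat, Rousettus aegyptiacus, in a study of convergent evolution of regulatory elements and proteins with vocal learning. ATAC-seq, which marks open chromatin by where a transposase can insert into DNA, was done on 10 tissues of 2 adult males (bats 1 and 3), giving 20 libraries. The tissues were 4 cortical areas (secondary auditory cortex, 2A; the orofacial and wing parts of primary motor cortex, ofM1 and wM1; premotor cortex, PreM), the caudate and putamen of the striatum, cerebellum, liver, pectoralis muscle and testis. Poly(A) RNA-seq was done on the 6 cortical and striatal regions of a female (bat 6) and a male (bat 7), giving 12 libraries, so each region had 1 library per animal in each assay and sex could not be separated from animal in the RNA data. The RNA libraries held 40790810 to 76023989 estimated reads, and read counts are given as CPM (reads scaled to a common library size). The ATAC-seq data were used as deposited peak lists, which held 155151 to 238945 separate intervals per library and covered 44 to 127 Mb.

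Peaks followed tissue. Between the 2 animals, the base pairs shared by 2 peak lists, as a fraction of those covered by either (the Jaccard index), averaged 0.492 ± 0.212 (SD, n = 10 pairs) for the same tissue and 0.267 ± 0.176 (SD, n = 90 pairs) for different tissues. The difference of 0.224 had a 2-sided permutation p of 1e-05 over 100000 rearrangements of the tissue labels of bat 3, the smallest they can give. Caudate (0.696), putamen (0.671), wM1 (0.648) and 2A (0.622) were shared most between the animals, followed by PreM (0.591), ofM1 (0.55) and cerebellum (0.522). Testis reached 0.287 and muscle 0.264. The liver lists shared 0.066, less than liver of bat 3 shared with each of the 9 other tissues of bat 1. This order holds for the whole lists, which differ in depth. With the 50000 strongest peaks of each library, cerebellum rose to 0.692, below caudate (0.716) and above putamen (0.678) and wM1 (0.643). Muscle then shared 0.438, testis 0.437 and liver 0.087. Liver of bat 1 had the weakest peaks, with a median enrichment of 2.23-fold over background among its 50000 strongest peaks, against 3.51-fold in liver of bat 3 and 6.94- to 12.8-fold in the 12 cortical and striatal libraries.

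**Figure D1:**
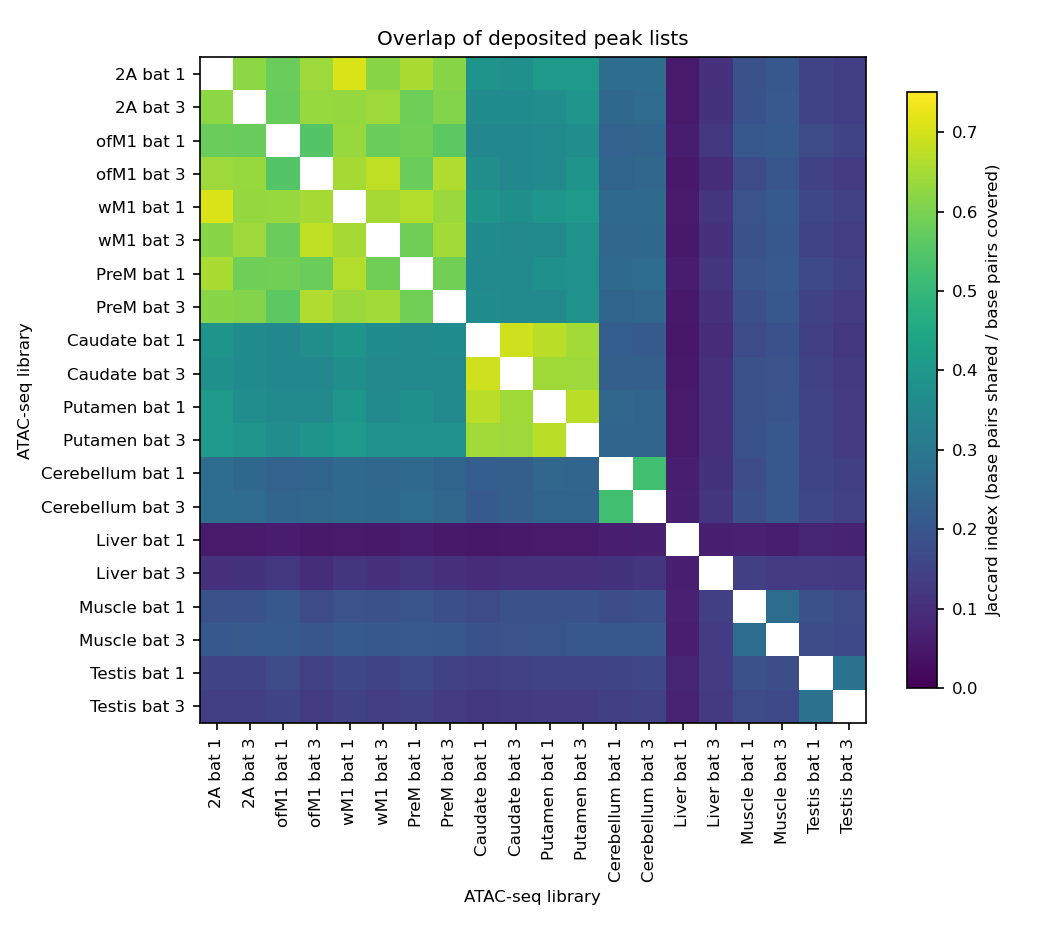
Jaccard index of base pairs shared by each pair of the 20 deposited ATAC-seq peak lists, ordered by tissue and then bat, with the colour scale from 0 to 0.75. The 8 cortical lists and the 4 striatal lists form 2 blocks, with indices of 0.349 to 0.403 between the blocks, and the row of liver of bat 1 stays at or below 0.078.

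Within the brain, cortex, striatum and cerebellum were separate, but the 4 cortical areas were not. Lists of different cortical areas shared 0.562 to 0.649 across animals, and lists of the same area 0.55 to 0.648. Over the 4 areas the mean for the same area was 0.603 ± 0.042 (SD, n = 4 pairs) and that for different areas 0.605 ± 0.0302 (SD, n = 12 pairs), with an exact permutation p of 0.71 (2-sided, 24 arrangements), in a comparison chosen after the data were seen. Different areas of the same animal shared a median of 0.644, against 0.602 across animals. Cortex and striatum shared 0.349 to 0.403, and cerebellum shared 0.216 to 0.27 with cortex or striatum. With the 6 cortical and striatal regions alone, same-region pairs exceeded other pairs by 0.148 (exact permutation p = 0.024, 720 arrangements), and with the 7 brain regions by 0.2 (exact permutation p = 0.0034, 5040 arrangements). The other pairs include those of cortex with striatum and, with 7 regions, of cerebellum with either. These differences therefore do not show that regions separate within cortex or within striatum.

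Regions open in 1 tissue were counted as those with a peak among the 50000 strongest in both animals and no peak of any rank in the 18 libraries of the other tissues. Testis had 2012 such regions, cerebellum 1957, muscle 1064 and liver 249. Pairs made of 1 animal of the tissue and the other animal of another tissue gave at most 80 for testis, 2 for cerebellum, 33 for muscle and 80 for liver over 18 pairs each. A region of such a pair must also have no peak in the remaining animal of either tissue. Peaks that recur in both animals of a tissue are thereby left out. These low counts follow largely from that rule and give no chance level. Caudate had 1 such region and the putamen and each of the 4 cortical areas had 0. The regions with the highest weaker -log10 p of the 2 animals were, in cerebellum, bases 58708490 to 58709187 of scaffold NW_023416306.1, with 15.7- and 19-fold enrichment, and, in muscle, bases 60472063 to 60473382 of scaffold NW_023416295.1, with 8.8- and 12.4-fold enrichment. In testis it was bases 33276 to 33832 of scaffold NW_023416310.1 (11.8- and 14.7-fold) and in liver bases 51361731 to 51362977 of scaffold NW_023416285.1 (2.98- and 4.74-fold). These folds are the peak caller's own values, the genome build of the coordinates is not given in the sources used here, and what is annotated at these positions was not analysed here. The lists were limited to 300000 rows and 15 reached that limit, so the weakest peak a list could hold ranged from a -log10 p of 2 in liver, muscle and testis of bat 3 to 12.3 in caudate of bat 1, and the counts depend on the thresholds. Counting every deposited peak as present gave 19309 regions for testis, 17901 for cerebellum, 4687 for muscle and 4108 for liver, and asking only for no strong peak elsewhere gave 7229, 9511, 5248 and 841. Reciprocal overlap of at least 50% lowered muscle to 609 and liver to 159. Without bat 1 or bat 3, where 1 list suffices, the counts were 12126 and 9218 for testis, 3971 and 4158 for cerebellum, 6510 and 5062 for muscle and 12742 and 22738 for liver.

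**Figure D2:**
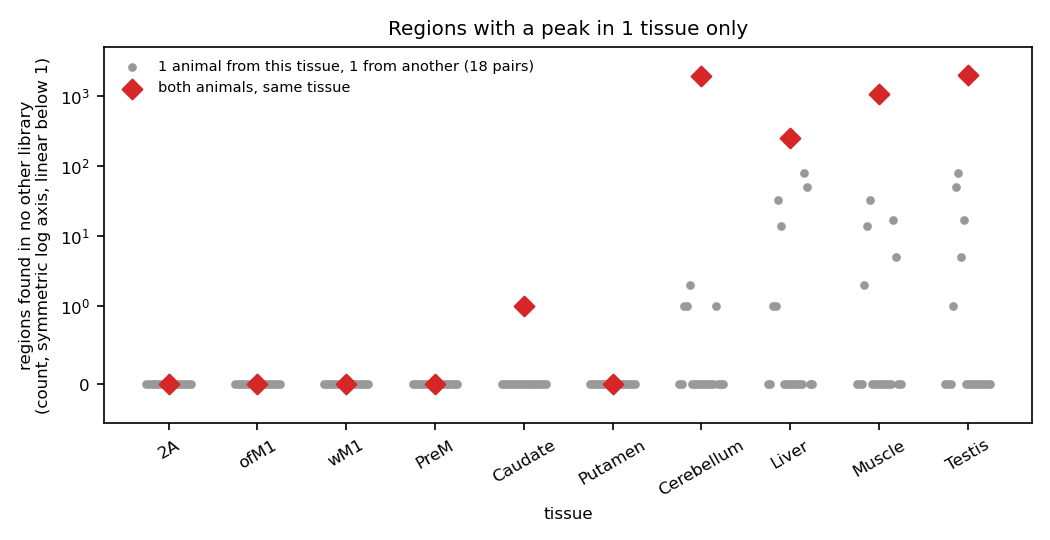
Number of regions with a peak among the 50000 strongest in 2 libraries and no deposited peak in the other 18, on a symmetric log axis that is linear below 1, for the 10 tissues. Diamonds are the 2 animals of the same tissue (2012 in testis, 249 in liver) and grey points are the 18 pairs that join 1 animal of that tissue with the other animal of another tissue, which reach at most 80. Regions of a grey point must also have no peak in the remaining animal of either tissue, so grey points give no chance level.

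Striatum and cortex each had many regions that the other lacked. A total of 3678 regions had a strong peak in all 4 striatal libraries and no peak in the 8 cortical ones, with a median width of 1029 bases and a median enrichment in the weakest library of 9.17-fold. Another 1730 had a strong peak in all 8 cortical libraries and none in the 4 striatal ones (median width 1125 bases, 6.8-fold). The 99 other divisions of these 12 libraries into 4 and 8 that were drawn gave 0 regions in either direction. Each of them has cortical libraries on both sides, so a region must have a strong peak in some cortical libraries and no peak in others. The zeros follow largely from that rule and give no chance level for the counts above. The strongest striatal region was at bases 16224513 to 16225896 of scaffold NW_023416295.1, enriched 17.9- to 22.4-fold in the 4 libraries, and the next at bases 58416573 to 58417719 of scaffold NW_023416284.1 (15.3- to 19.5-fold). The strongest cortical region was at bases 23595119 to 23596987 of scaffold NW_023416285.1, enriched 10.6- to 16.6-fold in the 8 libraries, and the next at bases 146240785 to 146242227 of scaffold NW_023416295.1 (10.8- to 15.9-fold). With every deposited peak as present the counts were 24950 and 21272, and with absence of a strong peak only they were 9279 and 5759.

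The orofacial and wing parts of primary motor cortex, the areas for moving the mouth and face and for moving the wing, did not separate by their peaks. No region was among the 50000 strongest in both animals of ofM1 and without any peak in both of wM1, and the converse also gave 0. Dividing the same 4 libraries by animal gave 60 regions for bat 1 and 13 for bat 3, and the crossed division gave 0 both ways. When every deposited peak counted as present, 1658 regions were found in ofM1 only and 4122 in wM1 only, but the division by animal then gave 11847 and 4957 and the crossed division 2556 and 3954.

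The RNA data were tested feature by feature. The files number 55974 features (mRNA followed by a number) and do not pair them with gene names, and 0 of the tested IDs were found in the gene table of assembly GCF_014176215.1 (mRouAeg1.p), so genes, gene lists and cell type markers could not be named. Of the features, 28713 passed the count filter. Feature lengths had a median of 18 kb and reached 1927 kb, and neighbouring numbers often carried nearly the same length: 31.4% of consecutively numbered pairs differed by at most 10% in length, against 4.7% of pairs 50 numbers apart. Of the 16639 features that reached 10 CPM in some library, 4696 had 0 reads in another. Counts are therefore given for single features and again after summing consecutively numbered features whose lengths differ by at most 10%, which was chosen after the data were seen.

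**Figure D3:**
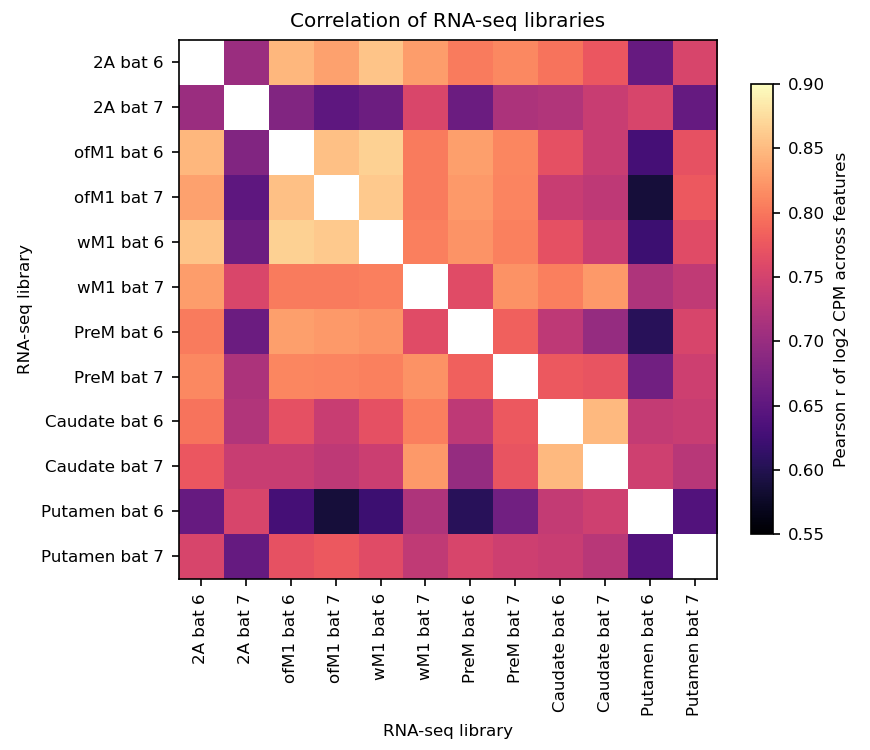
Pearson correlation of log2 CPM across the 28713 tested features for each pair of the 12 RNA-seq libraries, ordered by region and then bat, with the colour scale from 0.55 to 0.9. The 2 caudate libraries correlate at 0.849 and the 2 ofM1 libraries at 0.854, while putamen of bat 6 and 2A of bat 7 have the lowest medians with the other libraries, at 0.658 and 0.703.

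Cortex and striatum differed in 1403 features. In edgeR's quasi-likelihood test at an adjusted p under 0.05, 738 features were higher in cortex, by a median of 4.1-fold, and 665 were higher in striatum, by a median of 3.26-fold. All 1403 had the same direction in both animals. They were called on both animals together, so this follows largely from the selection and is not a separate replication. mRNA54137 averaged 121 ± 53.4 CPM (SD, n = 8) in cortex and had 0 reads in the 4 striatal libraries, at least 2080-fold higher with 3 reads per library as the floor (adjusted p = 0.000958). mRNA27167 averaged 58.9 ± 19 CPM (SD, n = 8) in cortex and also had 0 reads in striatum, at least 1020-fold higher (adjusted p = 9.08e-05). Conversely, mRNA11732 averaged 256 ± 140 CPM (SD, n = 4) in striatum and mRNA59902 averaged 91.1 ± 37.8 CPM (SD, n = 4), each with 0 reads in all 8 cortical libraries, at least 4520- and 1610-fold higher (adjusted p = 0.00847 and 0.00261). Summed with its neighbours, mRNA54137 was at 169 ± 20.9 CPM in cortex and 0.961 ± 0.339 CPM in striatum, a log2 difference of 7.48 ± 0.315 (SE, adjusted p = 1.75e-05).

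**Figure D4:**
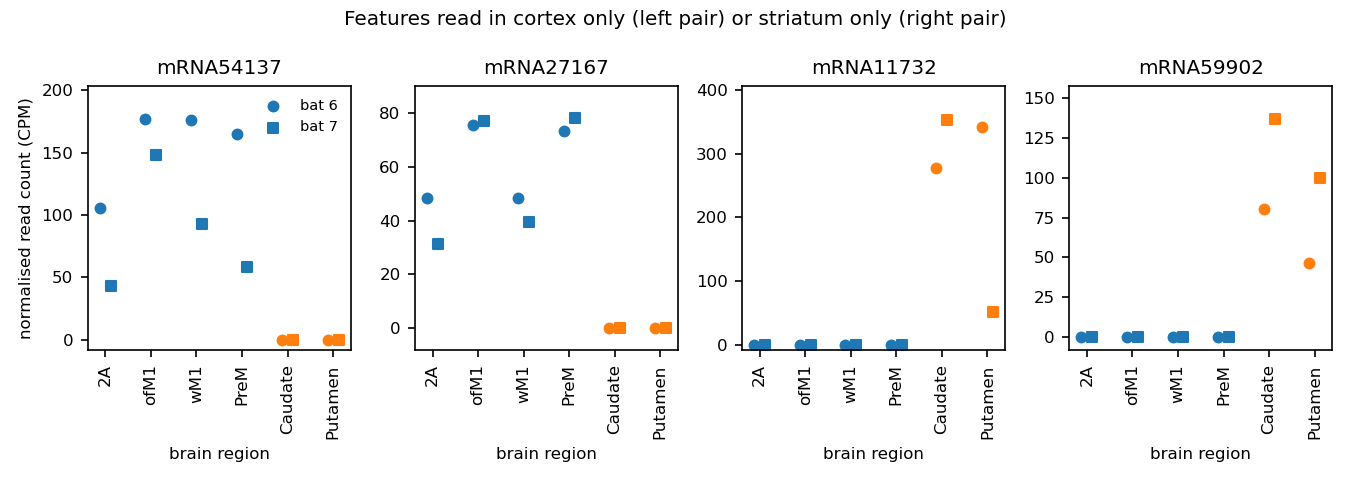
Normalised read count (CPM, linear axes from 0) of 4 features in the 12 RNA-seq libraries, with cortical regions in blue and striatal regions in orange, circles for bat 6 and squares for bat 7. mRNA54137 and mRNA27167 have 0 reads in the 4 striatal libraries, and mRNA11732 and mRNA59902 have 0 reads in the 8 cortical libraries, with mRNA11732 at 52 CPM in putamen of bat 7 and 278 to 353 CPM in the other 3 striatal libraries.

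After summing neighbours, 1861 of 24788 sums differed, 1031 of them higher in cortex. The count rose to 4259 without putamen of bat 7 and fell to between 552 and 860 without any 1 of the caudate, ofM1, PreM or wM1 libraries of either bat. DESeq2 called 6097. Without the 3 libraries that stood apart from the rest (both putamen libraries and 2A of bat 7), the comparison becomes cortex against caudate alone. It called 1514 features, 695 of them higher in cortex and 819 in caudate, with 911 among the 1403.

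Caudate and putamen differed in 52 features, of which 46 were higher in caudate and 6 in putamen. With the animal as a block the count was 14, all higher in caudate. In 43 of the 52, all libraries of 1 side had 0 reads. mRNA54169 averaged 76.9 ± 2.72 CPM (SD, n = 2) in caudate and 0 reads in putamen (adjusted p = 0.000456), but the sum of the 7 features of like length that hold it was 74.1 ± 3.26 CPM in caudate and 78.1 ± 35 CPM in putamen (adjusted p = 1). mRNA13826 averaged 94.1 ± 9.62 CPM in caudate and 0 in putamen (adjusted p = 0.0301, or 0.0659 with the block). Its sum of 2 features, at 90.6 ± 8.48 CPM in caudate and 49.7 ± 41.9 CPM in putamen, was not called (adjusted p = 0.791). Higher in putamen were mRNA55897, at 1.33 ± 0.12 CPM against 0 reads in caudate, and mRNA16056, at 1.64 ± 1.39 CPM against 0 (SD, n = 2; adjusted p = 0.0207 and 0.0398, or 0.0641 and 0.108 with the block). After summing, 26 sums were called, or 2 with the block. Relabelling the same 4 libraries by animal gave 9 calls and the crossed relabelling 4, against 52 for the regions. On sums they gave 1 and 1 calls against 26. In edgeR, 1304 and 1413 sums had an unadjusted p under 0.05, against 1873. Both relabellings put caudate and putamen in the same group, so they give no chance level. DESeq2 called 2522 single features, 1227 of them higher in caudate and 1295 in putamen. In edgeR the count was 0 with only the 4 libraries compared in the fit, and among features with a read in every library it was 31, of which 10 were higher in caudate and 21 in putamen, so the balance of directions depended on the features tested. The putamen libraries correlated at 0.639, the lowest of the 6 same-region pairs, and the count was 1164 without putamen of bat 7, 177 without putamen of bat 6, 21 without caudate of bat 6 and 4 without caudate of bat 7.

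The orofacial and wing parts of primary motor cortex differed in 9 features, 4 of them higher in ofM1 and 5 in wM1, and in 2 with the animal as a block. In 8 of the 9, both libraries of 1 side had 0 reads. mRNA55272 averaged 49.2 ± 2.17 CPM (SD, n = 2) in ofM1 and 0 in wM1 (adjusted p = 0.00202), while its sum of 7 features was 49.8 ± 2.35 CPM in ofM1 and 57.3 ± 21.7 CPM in wM1. mRNA9975 averaged 31.9 ± 3.35 CPM in ofM1 and 0 in wM1 (adjusted p = 0.041, or 0.264 with the block). In the other direction, mRNA30027 averaged 67.1 ± 15.8 CPM in wM1 and 0 in ofM1 (adjusted p = 0.00607), and mRNA30028 averaged 52.3 ± 18.6 CPM in wM1 and 0 in ofM1 (adjusted p = 0.041, or 0.236 with the block). Both belong to 1 sum of 4 features, at 150 ± 3.03 CPM in ofM1 and 124 ± 40.9 CPM in wM1 (adjusted p = 1). After summing, edgeR called 0 sums, with 151 at an unadjusted p under 0.05. DESeq2 called 879 single features, and edgeR called 0 with only the 4 libraries compared in the fit and 1 among features with a read in every library. Relabelling the same 4 libraries by animal gave 5 calls and the crossed relabelling 4, against 9 for the areas, but on sums they gave 2 and 1 calls against 0 and 531 and 172 sums at an unadjusted p under 0.05 against 151, and without ofM1 of bat 6 the count was 5.

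Secondary auditory cortex differed from the 3 motor areas in 11 features, 7 higher in 2A and 4 lower, and in 4 with the animal as a block. All 11 had 0 reads in at least 1 of the libraries compared, and 10 had a neighbour of like length. Summing left 1, which was lower in 2A, and 0 with the block (973 sums at an unadjusted p under 0.05 in edgeR). DESeq2 called 1633 single features, 990 of them higher in 2A. In edgeR the count was 26 without the 3 libraries that stood apart (7 higher in 2A and 19 lower), 15 with only the libraries compared in the fit (5 higher and 10 lower) and 0 among features with a read in every library. It was 175 without 2A of bat 6, which leaves 2A of bat 7 alone (22 higher and 153 lower), 7 without wM1 of bat 6 and 33 without PreM of bat 7 (28 higher and 5 lower).

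Premotor cortex differed from primary motor cortex in 10 features, 5 higher in PreM and 5 lower, and in 6 with the block. All 10 had 0 reads in at least 1 library compared, and edgeR called 0 after summing, with 287 sums at an unadjusted p under 0.05. DESeq2 called 837 single features. In edgeR the count was 0 with only the libraries compared in the fit, 0 among features with a read in every library and 35 without PreM of bat 7 (5 higher in PreM and 30 lower). In simulated counts with 200 features changed per comparison, the edgeR test found few of the changes. Of 50 features changed 16-fold, it called 1 for ofM1 against wM1, 0 for caudate against putamen and 13 for 2A against motor cortex. It called 9 of 50 for PreM against primary motor cortex and 20 of 50 for cortex against striatum. For cortex against striatum it called 1 of 50 changed 4-fold, while the real data gave 1403 calls with medians of 4.1- and 3.26-fold. The adjusted p of a feature depends on how many others change, so these shares do not give the recovery in the real data. Whether the low shares come from the replication was not tested. Differences within the cortex could be missed.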

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

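The tests of features detected, of held-out sums, of caudate scores on sums, of the enrichment of liver peaks and of summed neighbours were chosen after the results were seen. The tests over splits, of the caudate score and of the strongest peaks of liver of bat 1 were written before. Library measures were compared within the 8 cortical and the 4 striatal libraries of each assay in 18 sets of values, and chance flags about 1 in 20. The median correlation of 2A of bat 7 with the other RNA libraries, 0.703, lay apart from the next of the 8 cortical libraries at 0.762. It had 22898 features with a read, against 24714 to 26811 in the other 7 cortical libraries. A difference between cortex and striatum that itself differed between bat 6 and bat 7 was found for 31 features in edgeR's interaction test, 25 of them lower in bat 7 and 6 higher. Regions of the same animal served as replicates in that test, so the spread between animals was not measured. The animals also differ in sex, and the fit includes putamen and 2A of bat 7, which both stood apart from the other libraries of their class. Which of these accounts for the result was not tested.

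The division of the 12 RNA libraries into cortex and striatum called 1903 features in a fit with 2 groups. Of 100 divisions into 8 and 4 that were run, 2 called as many, the real one included, under the limit of 0.05 set beforehand. The highest other division called 3190 and the next 12. The highest put 2A of bat 7 in the place of putamen of bat 7, so the labelled division was not the one with the most calls. Both were among the 51 divisions with 2 libraries of each animal on the smaller side. Every division but the real one has cortical and striatal libraries together on its larger side. A difference between the tissues then adds to the spread within a group. The low counts follow in part from that and give no chance level for the 1903.

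The RNA library labelled putamen of bat 7 lay between cortex and striatum, and how near to either depended on the features used. Its closest library was ofM1 of bat 7 (r = 0.776). On features that set caudate apart from cortex in bat 6 it scored 0.226, where 0 is the mean of the cortical libraries of bat 7 and 1 its caudate, below 2A of bat 7 at 0.469. On sums of neighbouring features it scored 0.286, still below 2A at 0.365, and on those sums with a read in every library 0.539, above all 4 cortical libraries of bat 7 (-0.19 to 0.184 in 2A). Putamen of bat 6 scored 0.94, 0.863 and 0.756 on the 3 sets. For a swap with a cortical library of bat 7, the highest score, 0.469 in 2A, was under the limit of 0.5 set beforehand. That score cannot decide, since the mean that serves as 0 includes 2A itself, which lowers the score of 2A. A swap is argued against by 2A holding 17 of 21 sums read only in cortex (81%) and the putamen library 9 of 21 (42.9%). Exchanging these 2 labels nevertheless raised the calls. Of 24 sums read only in striatum the putamen library held 13 (54.2%) and 2A held 9 (37.5%), where the other 3 striatal libraries held 76.3 to 89.7% and wM1 of bat 7 held 38.5%. All these sums were chosen without the 3 libraries that stood apart (both putamen libraries and 2A of bat 7), so caudate alone stood for striatum in the choice. Cortical tissue in place of putamen is argued against by the same share of 42.9%, below the 81 to 100% of the 8 cortical libraries, each left out of the choice of sums it was scored on. Few detected features stay open: its 24390 features with a read exceeded only 2A of bat 7 among the cortical libraries, and that library stood apart itself. A difference between the animals, which also differ in sex, and a part of other tissue in the sample were not tested, and the labels were kept.

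The peak list of liver of bat 1 shared 0.066 with that of liver of bat 3. The whole list of liver of bat 1 shared slightly more with testis of bat 3 (0.073) and most with testis of bat 1 (0.078). The whole list thus does not speak against a wrong tissue label, while its strongest peaks lean against one. Of 939 of its 2000 strongest that were not in every other list, 59.4% were found in liver of bat 3, which covered the least sequence (44 Mb), more than in the other tissues of that animal (testis 53.1% in 72.2 Mb, muscle 49% in 75.9 Mb). Testis (65.6%), muscle (64.2%) and PreM (61.3%) of bat 1 held more, in larger lists of 82.5, 56.6 and 102 Mb. In a reverse check chosen afterwards, with neither liver in that filter, 175 of the strongest peaks of liver of bat 3 were kept. Of these, 61.1% were in liver of bat 1 (44.7 Mb). Among the tissues of bat 1, wM1 (66.9%) and 2A (62.3%) held more, in larger lists of 111 and 117 Mb. In bat 3 itself, testis held 74.3% and muscle 61.1%, and its other tissues held less. With so few peaks kept, small gaps between these shares carry little weight. A wrong label and a part of another tissue in the sample were therefore not excluded. Low signal over background may account for the small overlap, since the median enrichment of the top 50000 peaks of liver of bat 1, 2.23-fold, was the lowest of the 20 libraries. A difference between the livers of the animals was not tested.

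The 3 comparisons within the cortex made 30 calls, of 18 different features, 3 of which were called in all 3 comparisons. Reads moved between neighbouring features may account for many of them: after summing consecutively numbered features of like length, 1 was called in the 3 comparisons together. Part of that drop came from the changed fit. mRNA11583, higher in PreM than in primary motor cortex, had no such neighbour and kept its log2 difference of 8.91. Its edgeR adjusted p nevertheless rose from 0.0233 to 0.105. Likeness was judged by number and length, and shared sequence was not tested. Also open is whether isoforms of a gene differ between the areas, which sums cannot show.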

How the results depend on the processing

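The summing of neighbouring features, the features with a read in every library, the omission of the 3 libraries that stood apart, the overlap tests within the 4 cortical areas, within caudate and putamen and without liver, and the searches that did not require absence from liver of bat 1 were chosen after seeing the data. All other alternatives were planned. Except where stated, the cause was not tested.

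Cortex against striatum kept its count within 1.5 times under RLE scaling, no filter, the length offset, 2 groups, the block, summing and features with a read in every library, but DESeq2 gave 6097. DESeq2 gave 879 for ofM1 against wM1, 2522 for caudate against putamen, 1633 for 2A against motor cortex and 837 for PreM against primary motor cortex. The replicate block gave 2, 14, 4 and 6 in the same order, and moved no other count by over 1.5 times. With only the regions compared in the fit, ofM1 against wM1, caudate against putamen and PreM against primary motor cortex each gave 0, in fits with fewer libraries. Summing neighbouring features gave 0, 26, 1 and 0 in the order above, and with the replicate block 0, 2, 0 and 0. Features with a read in every library gave 1, 31, 0 and 0, with fewer features tested. Without the 3 libraries that stood apart, 2A against motor cortex gave 26.

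With 1 library left out, counts ran from 552 to 4259 for cortex against striatum, 5 to 11 for ofM1 against wM1, 4 to 1164 for caudate against putamen, 7 to 175 for 2A against motor cortex and 11 to 35 for PreM against primary motor cortex. Where this leaves a region with 1 library, that library is assumed to vary like the others. In the settings that test single features, named features kept their direction: 107 of their values also stayed under the threshold and 25 did not, as did 104 and 32 with a library left out. Sums that hold such a feature turned to a log2 difference of -0.204 for mRNA55272 and 0.272 for mRNA30027 and mRNA30028 in ofM1 against wM1, -0.0764 for mRNA54169 in caudate against putamen, and -0.33 for mRNA30027, 0.156 for mRNA5878 and 0.0897 for mRNA13780 in 2A against motor cortex, all with an edgeR adjusted p of at least 0.981.

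The same-tissue overlap stayed positive in every other setting but turned to -0.00263 for the 4 cortical areas and to -0.00326 for their top 50000 peaks. For caudate and putamen only it was 0.039, where the 2 arrangements cannot give an exact permutation p under 1. In the order liver, muscle, testis and cerebellum, presence by every deposited peak gave 4108, 4687, 19309 and 17901, and absence as no top 50000 peak 841, 5248, 7229 and 9511. Presence by -log10 q of at least 2 gave 2222 for muscle, 9135 for testis and 17901 for cerebellum, and reciprocal overlap of at least 50% gave 159 for liver and 609 for muscle. For striatum not cortex, cortex not striatum and ofM1 against wM1, the q threshold gave 24950, 21214 and 5722, every deposited peak 24950, 21272 and 5780, and absence of a top peak 9279, 5759 and 1204. The rises follow from construction, since more peaks count as present or more regions as absent, and the falls with reciprocal overlap from its stricter demand on sharing. With 1 animal left out, so that 1 list suffices, counts ran from 12742 to 22738 for liver, 5062 to 6510 for muscle, 9218 to 12126 for testis, 3971 to 4158 for cerebellum, 5055 to 5677 for striatum not cortex, 2753 to 3252 for cortex not striatum and 9 to 15 for ofM1 against wM1.

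The 3 alternatives of the gene list tests and all those of the promoter and link tests were not run, for want of gene names and an annotation of the build. No read depth goes with the peak lists, and absence from a list at its limit of 300000 is not absence of signal.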

Other observations

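A peak among the 50000 strongest was found in all 20 libraries at 4838 regions, and at 10616 when liver of bat 1 was left out. In all 14 brain libraries it was found at 17617 regions, of which 102 had no deposited peak in liver, muscle or testis. Against the other 6 brain regions, cerebellum had 4555 regions of its own, caudate 3, putamen 1 and each of the 4 cortical areas 0, while pairs that joined different brain regions of the 2 animals gave 0. Such pairs leave out peaks that recur in both animals of a brain region, so their zeros follow largely from that rule.

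Cerebellum-only regions were uneven over the scaffolds. Scaffold NW_023416312.1 held 159 of the 1957, or 8.12%, but 3.08% of all regions with a strong cerebellar peak in both animals (odds ratio 3.02, Fisher's exact test p = 5.8e-29, 9e-27 after Benjamini-Hochberg adjustment over 155 tests of 6 sets of regions by scaffold). They lay in 66 windows of 1 Mb with at most 8 in a window. On the same scaffold lay 10 of the 1730 cortical regions absent from striatum (0.578% against 1.84%, odds ratio 0.298, adjusted p = 0.00017) and 12 of the 2012 testis-only regions (0.596% against 1.27%, odds ratio 0.449, adjusted p = 0.033). Testis-only regions were more frequent on scaffold NW_023416293.1, with 55 (2.73% against 1.43%, odds ratio 2.07, adjusted p = 0.00015), and striatal regions absent from cortex on scaffold NW_023416286.1, with 246 (6.69% against 4.68%, odds ratio 1.54, adjusted p = 5.7e-07). Regions close to each other are not independent, so these p-values are too small. All were computed after the data were seen.

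Putamen of bat 6 and 2A of bat 7, from different regions and animals, lacked the same features. Of the features with 0 reads in exactly 2 RNA libraries and at least 5 CPM in the other 10, 116 were at 0 in this pair, and the next pair of libraries had 17. These were also the 2 libraries with the fewest features with a read (20880 and 22898), so some excess of shared zeros is to be expected. Whether that accounts for 116 was not tested. Putamen of bat 7, the next lowest at 24390 features, shared 10 such features with putamen of bat 6 and 13 with 2A of bat 7. The library closest to putamen of bat 6 was also 2A of bat 7 (r = 0.755).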
